A study of Mus musculus with 16 samples.

How the data were processed

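Airway epithelial cells of C57BL/6 mice were grown at an air-liquid interface in 16 cultures, and RNA of each was hybridised to 1 Affymetrix expression array. The cultures form 4 groups of 4 arrays: Mmp7-null or wild-type, each uninjured or scratched. Scratched cultures received 3 scratches, and serum was withdrawn from all cultures for 24 hours before harvest. The labels do not say how long after scratching the RNA was taken, or which cultures came from the same animal. All p-values therefore measure only the spread between these 16 cultures.

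The deposited table holds intensities on a linear scale, which the authors obtained with RMA (background correction, normalization between arrays and summary of probes per probe set); the version was not given. It lists 45101 probe sets. That number belongs to the larger 430 2.0 array, as does the probe annotation supplied for the table, whereas the labels name the 430A 2.0 array; the probe sets in the table were used as they are. Intensities were converted to log2 before any test, and no further normalization was applied. Array medians ran from 9.357 to 10.16 on the linear scale.

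Of the 45037 probe sets other than controls, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Those with several or none were left out of the gene-level tests. All 64 control probe sets were left out, including 13 that carry a gene symbol; this last exclusion was made after a first count of genes had been seen. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays, and 9010 genes had more than 1 probe set. No filter on dim genes was applied. Control transcripts absent from a given array gave a background estimate, with a 95th percentile of 2.97 on the log2 scale, and the mean of 11655 genes (64.1%) lay above it.

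Differences were tested in R 4.3.3 with limma 3.58.1. One linear model with a mean per group was fitted to all 16 arrays, which gave 12 residual degrees of freedom, and moderated by eBayes. The 5 comparisons were scratched against uninjured in each genotype, Mmp7-null against wild-type in each state, and the difference between the genotypes' scratch responses. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Errors given with log2 fold changes are the model's standard errors. The median standard error over genes above background was 0.1 on the log2 scale for the scratch and genotype comparisons. It was 0.14 for the difference between scratch responses. The number of arrays limits the precision.

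Lists of genes for airway and other cell types, cell cycle, wound response, inflammation, metabolism, metalloproteinases and the neighbours of Mmp7 on chromosome 9 were fixed from general knowledge before the data were examined, as were the comparisons, the alternative settings and the rule for naming genes. The 34 lists held 976 measured genes. Each was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over all 170 tests. Camera with an estimated correlation was run beside it. The preset test made 64 calls and the estimated correlation kept 8 of them, so list results are given with both. The rule names Mmp7, the 10 largest called changes each way with no overlap between groups, up to 4 members per list with a call, and all called metalloproteinase and chromosome 9 list members. The rule gives 606 pairs of gene and comparison; the text names part of them, and the list members among these were picked after their values were seen.

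Spiked-in control transcripts separate the arrays into 3 sets. The Lys control was present on 4 Mmp7-null arrays (uninjured 1 and 2, scratched 1 and 4). The Phe control was present on 6 arrays (Mmp7-null uninjured 3 and 4, Mmp7-null scratched 2 and 3, and replicate 1 of both wild-type groups). The Trpn control was present on the 6 remaining wild-type arrays. What the controls stand for is not stated, so the sets were treated as a possible batch. Genotypes share only the Phe set, and list medians and counts of calls with the set as a block and within a set are given with the genotype differences; for named genes the text says which kept their call with the block. Comparisons within a set come from a model with a mean per group and set, so their spread is that of all arrays with a replicate in their group and set. These were added after the data had been seen. So was a repeat without 3 doubtful arrays (wild-type scratched 3 and 4, Mmp7-null scratched 1), which have the 2 lowest upper quartiles of signal and the largest gap between the ends of the actin control transcript; this criterion was set after the arrays had been seen to lie apart.

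The alternative settings were the replicate number as a block, the 8 arrays of the groups compared, removal of the dimmest 40% of genes, other treatments of multiple probe sets, a trended and robust variance, array weights, repeated quantile normalization, median centring, a fold threshold of 1.5, and leaving out each array. Residuals gave little sign that replicate numbers pair arrays across groups: of 24 same-number pairs, 4 had a correlation above 0.1. The highest, 0.34 and 0.18, were between uninjured and scratched wild-type cultures (replicates 3 and 2), where replicates 1 and 4 gave -0.10 and -0.03. Pairing within a genotype is therefore not excluded. Replicate numbers were not used as a block in the reported values. Single values were compared by exact two-sided permutation tests, whose smallest p for 4 against 4 is 0.0286. The gene test was tested on simulated data with independent noise. The changed genes were drawn only from those above background, so the rates of recovery do not cover dim genes. It recovered 62.1% of log2 changes of 0.5 and 92.8% of changes of 1 for the wild-type scratch comparison. For the difference between scratch responses it recovered 31.6% and 81.5%. False calls made up to 7.66% of the calls.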

Results

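Gene expression was measured in cultured mouse airway epithelium with and without a scratch injury, in wild-type cells and in cells lacking Mmp7 (matrilysin, a secreted metalloproteinase of injured epithelium). There were 4 cultures in each of 4 groups, with 1 array per culture. The first principal component (24.3% of the variance) separated the genotypes and the second (23.6%) separated scratched from uninjured cultures. Values below are log2 fold changes with the standard error from limma and the adjusted p, with n = 4 cultures per group; levels are group means of log2 intensity with their SD. Every gene described as among the largest changes had all 4 arrays of one group above all 4 of the other. The naming rule required this, so it is not added evidence. Of all 18193 genes, 1824 were separated in this way for scratch in wild-type and 2332 for scratch in Mmp7-null cultures. For genotype the numbers were 2122 in uninjured and 5951 in scratched cultures, so the requirement selects little in the last comparison. The number of list calls at the preset correlation was reached by 3 of the 35 splits of the arrays for scratch in Mmp7-null cultures, by 2 of 35 for genotype in uninjured cultures and by 27 of 35 for genotype in scratched cultures, the real split included. In these comparisons the number of list calls is no larger than some other splits give. Splits that exchange 1 array between the groups keep part of any real difference, so they cannot show that the calls are due to chance. Lists are described by their counts of genes, with the list tests beside them.

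The first comparison asks what a scratch does to wild-type airway epithelium. On scratching 40 of 47 mitotic genes rose, and single genes of chemokines and mucus were among the largest changes. The chemokine precursor Ppbp (Entrez 57349, chromosome 5) went from 5.04 ± 0.58 to 9.66 ± 0.33, a log2 fold change of 4.62 (SE 0.39, adjusted p = 9.7e-06). The mucin Muc5b rose by 3.26 (SE 0.48, adjusted p = 0.00097) and Agr2, a protein disulfide isomerase needed for mucin folding, by 2.54 (SE 0.13, adjusted p = 1.6e-07). Ptgs2, the inducible prostaglandin synthase, rose by 2.54 (SE 0.19, adjusted p = 3.5e-06).

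Of 47 measured genes for G2 and mitosis, 40 rose and 7 did not pass, and 46 passed when adjusted over the list alone. Their median change was 1.06 (adjusted p = 1e-66 at the preset correlation and 0.0081 with an estimated one). Cenpa, the centromeric histone, rose by 2.37 (SE 0.16, adjusted p = 1.4e-06), Ube2c by 2.14 (SE 0.13, adjusted p = 5.8e-07), Ccnb2 (cyclin B2) by 2.03 and Prc1 by 1.19. The 38 genes for G1/S and replication did not move with them: 2 fell and 36 did not pass, with a median of -0.12 (adjusted p = 0.032; adjusted p = 0.72 with an estimated correlation), and the list's direction turned without the 3 doubtful arrays (adjusted p = 0.75). Cholesterol synthesis was the other list called both ways (adjusted p = 9.6e-12 and 0.014): 9 of 20 genes rose, 1 fell and 10 did not pass, and 15 rose and 1 fell when adjusted over the list alone. Among them Tm7sf2 rose by 1.07, Hsd17b7 by 0.99 and Fdft1, the first committed enzyme of sterol synthesis, by 0.64.

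Chemokine and cytokine genes rose in 13 of 43 cases (16 adjusted over the list alone; adjusted p = 8.8e-11, and adjusted p = 0.065 with an estimated correlation). Csf2, a myeloid growth factor, rose by 1.38, Nfkbiz by 0.84, Tnfaip3 by 0.78 (a dimmer probe set gave 0.15) and Cxcl5 by 0.56. Goblet and mucus genes rose in 5 of 22 cases (5 adjusted over the list alone; adjusted p = 4.2e-05, and adjusted p = 0.066 with an estimated correlation). Of the immediate early and AP-1 genes, 9 of 36 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 4.2e-05, and adjusted p = 0.15 with an estimated correlation). These included Ccn1, a matricellular target of stretch and wounding, at 1.57, and Dusp1 at 0.93. Genes of the wound edge rose in 8 of 48 cases (12 higher and 5 lower adjusted over the list alone; adjusted p = 0.00078, and adjusted p = 0.37 with an estimated correlation), among them Tnc (tenascin C) at 1.87 and Actn1 at 0.84. Matrix genes rose in 5 of 36 cases (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.46 with an estimated correlation), led by Fn1 (fibronectin) at 2.16 (SE 0.11, adjusted p = 1.4e-07) and Dcn at 1.58.

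Other large increases were in Dmbt1 (3.53), Kcne2, a potassium channel subunit (2.77), Ifi27l2a (2.70), Wfdc1 (2.47) and Lrg1 (2.33). The largest decreases were in the potassium channel Kcnk2 (-2.07, SE 0.31, adjusted p = 0.001), Slc6a15 (-1.5), Fhod3 (-1.46), Ppp2r2b (-1.41), Rasl11a (-1.35) and H3f3b (-1.29), followed by Akr1c14 (-1.20), Esam (-1.15), Dclk1 (-1.12) and Id3 (-1.09). Of 24 basal cell genes 1 rose, 3 fell and 20 did not pass, and the list was not called (adjusted p = 0.25): Krt17 rose by 0.71, while Krt5 fell by 0.80 and Trp63, the basal cell master regulator, by 0.48. Of 57 multiciliated cell genes 1 rose, 3 fell and 53 did not pass, and the list was not called (adjusted p = 0.092); Tuba1a rose by 0.35, and Deup1 and Myb fell by 0.58 and 0.54. Leukocyte markers rose in 2 of 28 cases (median 0.03; adjusted p = 0.0022, and adjusted p = 0.58 with an estimated correlation), with the macrophage marker Cd68 at 1.03. Smooth muscle and cartilage markers rose in 1 of 17 cases (median 0.04; adjusted p = 0.024, and adjusted p = 0.73 with an estimated correlation): the actin Acta2 by 1.07 (adjusted p = 0.052 with the spike-in set as a block). Further lists called at the preset correlation were fatty acid synthesis (median 0.10), ribosomal proteins (-0.09), unfolded protein and heat shock (-0.07) and junctions (-0.05). All were lost with an estimated correlation (smallest adjusted p = 0.37). Of the metalloproteinases and their inhibitors Timp1 rose (0.78, adjusted p = 0.041, and 0.07 with the block), and of the chromosome 9 neighbours of Mmp7 the antiapoptotic gene Birc3 rose by 0.61 and Yap1 by 0.27 (a dimmer Yap1 probe set gave -0.03). For other genes named here with a probe set more than 1.5 times smaller, the remaining probe sets gave 0.79 (Cenpa), 0.90 and 0.36 (Nfkbiz), -0.36, -0.19 and -0.18 (Trp63), 0.04 (Birc3), 0.69 and 0.43 (Actn1), 0.63 (Hsd17b7), 1.65, 1.03 and 0.95 (Ccn1), and -1.26, -1.07, -0.98, -0.62, -0.60 and -0.58 (Dclk1).

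In all, 883 genes passed, 464 higher and 419 lower. With each array centred on its median the split was 344 higher and 595 lower. With the spike-in set as a block 764 genes passed, and within the Trpn arrays (3 against 3) 418; of 46 called genes named here 44 passed with the block. The sets are spread alike over both states of a genotype, so the block cannot change the size of a scratch response.

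The same comparison in Mmp7-null cultures asks whether the injury response is present in them too. Here 24 of 47 mitotic, 13 of 20 sterol synthesis and 19 of 43 chemokine and cytokine genes rose. Ppbp rose by 3.87 (SE 0.39, adjusted p = 0.00013), from 6.32 ± 0.97 to 10.19 ± 0.14. Ifi27l2a rose by 3.20 (SE 0.48, adjusted p = 0.002), Muc5b by 2.64 (SE 0.48, adjusted p = 0.0068), Serpinb2, a plasminogen activator inhibitor, by 2.11 (SE 0.28, adjusted p = 9e-04) and Ptgs2 by 2.08 (SE 0.19, adjusted p = 7.2e-05).

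Of the 47 mitotic genes 24 rose and 23 did not pass, 34 rose when adjusted over the list alone, and the median was 0.51 (adjusted p = 7.8e-37, and 0.029 with an estimated correlation). Ube2c rose by 1.58, Ccnb2 by 1.23 and Kif20a by 1.03. Sterol synthesis genes rose in 13 of 20 cases with 1 falling (16 and 1 adjusted over the list alone; adjusted p = 4.1e-22 and 0.0028), including Mvd (0.73), Fdft1 (0.55) and Srebf2, the regulator of the pathway (0.74; its other probe set gave 0.32). Chemokine and cytokine genes rose in 19 of 43 cases (22 adjusted over the list alone; adjusted p = 8.9e-24 and 0.0089), such as Tnfaip2 (0.98), Cxcl5 (0.86) and Nfkbiz (0.62). Immediate early and AP-1 genes rose in 9 of 36 cases (15 higher and 1 lower adjusted over the list alone; adjusted p = 8e-11 and 0.029). Ccn1 was at 1.64 by its brightest probe set, 1.67 by another and -0.08 and -0.40 by the remaining ones.

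Interferon response genes had a median of 0.56, but 5 of 42 passed over all genes and 28 passed when adjusted over the list alone (adjusted p = 5.9e-21, and adjusted p = 0.27 with an estimated correlation). Ifitm1 rose by 1.03, Rtp4 by 1.43 and Zbp1 by 0.95; Rtp4 (adjusted p = 0.059) and Zbp1 (0.054) did not pass with the spike-in set as a block. Matrix genes rose in 4 of 36 cases (7 adjusted over the list alone; adjusted p = 6.7e-05, and adjusted p = 0.26 with an estimated correlation), among them Fn1 at 1.63 and Timp1 at 1.44. Ribosomal protein genes fell in 3 of 31 cases (12 adjusted over the list alone), with a median of -0.14 (adjusted p = 4.7e-08, and adjusted p = 0.39 with an estimated correlation). Goblet and mucus genes rose in 6 of 22 cases (6 adjusted over the list alone; median -0.01 and mean 0.37; adjusted p = 0.00016, and adjusted p = 0.09 with an estimated correlation), with Agr2 at 1.44 and Clca3a2 at 1.33.

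Further increases were in Lrg1 (2.28), Dmbt1 (2.23), Calcb (1.94), Fgd3 (1.68) and Tnc (1.65). The largest decreases were in H3f3b (-1.97), Anxa10 (-1.32), Slc6a15 (-1.32), Cst6 (-1.25), Id3 (-1.14), the caveolar protein Cav1 (-1.09), Sult1a1 (-1.06), the aldehyde dehydrogenase Aldh3a1 (-1.03), Akr1c14 (-0.99) and Rnf144b (-0.93). Of the metalloproteinase list Adam8 also rose (0.50). On chromosome 9 Birc3 (0.53) and Yap1 (0.25; adjusted p = 0.053 with the block) rose and Casp12 fell by 0.32. Other probe sets were more than 1.5 times smaller for Anxa10 (-0.28), Clca3a2 (0.20), Birc3 (0.00), Yap1 (0.06) and Rtp4 (0.89). Further lists called at the preset correlation were multiciliated cell (median 0.07), wound edge (0.07), TGF-beta (0.08), hypoxia (0.06), fatty acid synthesis (0.24), oxidative phosphorylation (-0.11), metalloproteinases (0.00) and Wnt and Notch (0.01), all lost with an estimated correlation (smallest adjusted p = 0.1).

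In Mmp7-null cultures 859 genes passed, 413 higher and 446 lower. Leaving out Mmp7-null uninjured replicate 2 or 3 gave 516 and 528 genes, and the 8 Mmp7-null arrays alone gave 402. With the spike-in set as a block 700 genes passed, with 286 within the Lys arrays and 79 within the Phe arrays (2 against 2 each).

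The scratch responses of the genotypes, which share no arrays, correlated across genes with r = 0.60 (0.56 to 0.60 leaving out 1 array). The slope of Mmp7-null on wild-type over all genes was 0.55 (0.50 to 0.57). Noise in the wild-type values lowers such a slope, so it does not measure how large the Mmp7-null response is relative to wild-type. Genes are not independent replicates, so no p is given. Both comparisons called 349 genes, 208 higher in both and 137 lower in both. From the counts 10.5 and 10.3 were expected if calls were independent over all genes. Both comparisons share each gene's estimated spread and dim genes are seldom called, so part of the overlap is built in.

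The next comparison asks how Mmp7-null epithelium differs before injury. In uninjured Mmp7-null cultures 34 of 57 multiciliated cell genes were higher than in wild-type ones, and single alveolar and junctional genes were among the largest decreases. Lrrc23, a gene of the axoneme of motile cilia, was higher by 0.95 (SE 0.09, adjusted p = 7e-05), at 10.99 ± 0.10 against 10.04 ± 0.11. Deup1, which builds centrioles in multiciliated cells, was higher by 0.83 (SE 0.08, adjusted p = 7e-05). Ager, a marker of alveolar type 1 cells, was lower, at -2.29 (SE 0.21, adjusted p = 8.1e-05), and the neutrophil chemokine Cxcl1 was lower, at -2.60 (SE 0.29, adjusted p = 0.00044).

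Of 57 multiciliated cell genes 34 were higher and 23 did not pass, and 49 were higher when adjusted over the list alone. Their median was 0.52 (adjusted p = 5.3e-47, and 0.042 with an estimated correlation). With the spike-in set as a block the median was 0.55, and within the Phe arrays it was 0.46. Cfap126 was at 0.70 and Myb at 0.67. Mitotic genes were higher in 12 of 47 cases (20 adjusted over the list alone), with a median of 0.30 (adjusted p = 8.5e-16, and adjusted p = 0.15 with an estimated correlation); Aurka was at 0.81, Cdk1 at 0.53 and Cks2 at 0.48. Junction and polarity genes were lower in 8 of 30 cases (14 adjusted over the list alone; median -0.20; adjusted p = 6.9e-09, and adjusted p = 0.11 with an estimated correlation). Among these Cldn18 was lower, at -2.46 (SE 0.15, adjusted p = 3.4e-06), with its Mmp7-null level of 2.63 at background, which limits the size that can be measured; Cldn23 was at -0.62 and Jup at -0.52.

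Class II antigen presentation genes were lower in 3 of 8 cases (3 adjusted over the list alone; adjusted p = 0.00076, and adjusted p = 0.069 with an estimated correlation): H2-Aa at -1.38, Cd74 at -1.24 and H2-Ab1 at -1.03. Blocking on the spike-in set gave -1.44 (adjusted p = 0.2), -0.94 (adjusted p = 0.18) and -0.56 (adjusted p = 0.18) in the same order, and H2-Ab1 was at -0.39 within the Phe arrays. The class I genes B2m (-0.80), H2-K1 (-0.46) and H2-D1 (-0.44) were lower too; they were the 3 called members of the 42 interferon response genes (median -0.30; 4 adjusted over the list alone; adjusted p = 0.00051, and adjusted p = 0.76 with an estimated correlation). Basal cell genes were lower in 4 of 24 cases (9 adjusted over the list alone; median -0.17; adjusted p = 0.0015, and adjusted p = 0.37 with an estimated correlation), including Igfbp2 at -1.81, Sfn at -0.65 and Krt5 at -0.36. Igfbp2 is also counted in the alveolar type 1 set described further below. With the spike-in set as a block Igfbp2 kept its call (adjusted p = 0.044), and Sfn (0.15) and Krt5 (0.39) did not. Chemokine and cytokine genes included 4 higher and 6 lower of 43 (4 and 9 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation); complement factor Cfb was at -1.58. Immediate early genes Atf3 (-0.95) and Phlda1 (-0.58) were lower, and 6 of their 36 list members passed (6 adjusted over the list alone; adjusted p = 3e-05, and adjusted p = 0.14 with an estimated correlation). The BMP and TGF-beta targets Id3 (-1.34) and Id1 (-0.64) belonged to 10 lower and 2 higher of 30 genes (13 and 3 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.31 with an estimated correlation).

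The list medians with the spike-in set as a block, and then within the Phe arrays, were 0.20 and 0.20 for mitosis, -0.11 and -0.18 for junctions, -0.29 and -0.17 for class II (-0.37 without the block), -0.21 and -0.28 for interferon, -0.12 and -0.09 for basal cells, -0.08 and -0.05 for chemokines (-0.05 without it), -0.08 and -0.04 for immediate early genes (-0.11 without it), and -0.14 and -0.11 for TGF-beta genes (-0.05 without it). The chemokine (adjusted p = 0.3) and interferon (adjusted p = 0.17) lists were not called with the block. Further lists called at the preset correlation were hypoxia (median -0.13), fatty acid synthesis (-0.10), xenobiotic response (-0.13), oxidative phosphorylation (0.06), G1/S (0.11) and Wnt and Notch (-0.04). All were lost with an estimated correlation (smallest adjusted p = 0.15). With the block at the preset correlation, fatty acid synthesis (adjusted p = 0.099), G1/S (0.14) and Wnt and Notch (0.12) were not called either.

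The 10 largest increases were in Tnc (2.00), Sema5a (1.67; another probe set gave 0.75), Ccdc18 (1.63; its 2 other, dimmer probe sets gave -0.01 and 0.03), Atg9b (1.54), Lgals1 (1.5), the surfactant protein gene Sftpc (1.5; a dimmer probe set gave -0.08), Ube2u (1.46), 6330403K07Rik (1.44), Acta2 (1.37) and Rptoros (1.33). The 10 largest decreases were in Cxcl1, Gpm6a (-2.59), Cldn18, Ager, Spock2 (-1.93), Igfbp2, Esam (-1.78), Ndnf (-1.73), Cybrd1 (-1.60) and Prrg3 (-1.58); the Mmp7-null levels of Gpm6a (2.66) and H2-Ab1 (2.89) and the wild-type level of Sema5a (2.94) lay at background. For further genes named here with a probe set more than 1.5 times smaller, the other probe sets gave -1.39 (Gpm6a), -0.70 (Cybrd1), -0.68 (H2-Aa), -0.46, -0.58 and -0.45 with dimmer ones at -0.22 and -0.07 (H2-D1), -0.94 and -0.55 (Mmp14), 0.16 (Casp12), and -0.34, -0.25, -0.20 and -0.12 (Timp2). Among alveolar markers Hopx was at -0.34, and 1 was higher and 2 were lower of 15 (1 and 4 adjusted over the list alone; adjusted p = 0.057). Metalloproteinase family genes were lower in 5 of 30 cases: Mmp23 (-0.87), Mmp14, a membrane collagenase (-0.84), Timp3 (-0.58), Adam9 (-0.33) and Timp2 (-0.30). None of the 5 passed with the spike-in set as a block (adjusted p = 0.16, 0.47, 0.4, 0.26 and 0.7). At the preset correlation their list was not called without the block (adjusted p = 0.057) but was called with it (adjusted p = 0.025). With an estimated correlation and no block the adjusted p was 0.53. Of 41 chromosome 9 neighbours of Mmp7, Casp4, an inflammatory caspase, was at -1.37 (SE 0.11, adjusted p = 3.6e-05) and Pdgfd at -1.20 (SE 0.31, adjusted p = 0.04; with the spike-in set as a block -1.11, SE 0.46, adjusted p = 0.47), while Gucy1a2 (0.58), Aasdhppt (0.37; its 3 other probe sets gave 0.44, 0.47 and -0.27) and Casp12 (0.31) were higher.

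In all, 872 genes passed, 418 higher and 454 lower. Leaving out Mmp7-null uninjured replicate 1 gave 480 and leaving out wild-type uninjured replicate 1 gave 534, while 1310 passed without the 3 doubtful arrays. With the spike-in set as a block 57 genes passed (33 higher, 24 lower), within the Phe arrays (2 against 1) 42 passed, and Lys arrays against Trpn arrays gave 430. Between sets of the same genotype, averaged over both states, Phe minus Lys called 1 gene in Mmp7-null cultures (4 against 4 arrays) and Phe minus Trpn called 28 in wild-type ones (2 against 6). The block raises the standard error of this comparison 1.47 times, and of 53 called genes named here 16 passed with it: Cldn18, Ager, Cxcl1, Casp4, Deup1, Lrrc23, Myb, Cfap126, Cks2, Esam, Gpm6a, Igfbp2, Prrg3, Rptoros, Sftpc and Tnc. The others lost their call. The 53 log2 fold changes had a median ratio of 0.92 to those without the block. The Phe arrays, which share nothing with the Lys and Trpn arrays, gave the same sign for 419 of the 430 genes (97.4%). Over all genes the differences within the Phe arrays and of Lys against Trpn arrays correlated less closely, with r = 0.63. Sign alone does not show that the sizes match.

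The fourth comparison asks how the genotypes differ after scratching. Here 47 of 57 multiciliated cell genes were higher in Mmp7-null cultures. Myb, a regulator of multiciliated cell differentiation, was higher by 1.07 (SE 0.06, adjusted p = 5.7e-07), Deup1 by 1.05 (SE 0.08, adjusted p = 9.8e-06), Lrrc23 by 1.01 (SE 0.09, adjusted p = 3.6e-05) and the radial spoke gene Rsph1 by 0.91. Cxcl1 was lower, at -2.70 (SE 0.29, adjusted p = 0.00018) and Ager at -2.35 (SE 0.21, adjusted p = 6e-05).

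Of the 57 multiciliated genes 47 were higher and 10 did not pass; adjusted over the list alone 51 were higher and 1 lower. The median was 0.74 (adjusted p = 2.4e-59, and 0.028 with an estimated correlation), 0.78 with the spike-in set as a block and 0.88 within the Phe arrays. Mitotic genes were lower in 6 of 47 cases and higher in 2 (24 and 2 adjusted over the list alone; median -0.35; adjusted p = 0.00059, and adjusted p = 0.62 with an estimated correlation), among them Ube2c (-0.59), Cdc25b (-0.59), Ect2 (-0.45) and Birc5 (-0.44). Xenobiotic and NRF2 response genes were lower in 6 of 27 cases (13 lower and 1 higher adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.6 with an estimated correlation). Medians with the spike-in set as a block, and then within the Phe arrays, were -0.44 and -0.43 for mitosis, -0.11 and -0.14 for xenobiotic genes (-0.15 without the block), 0.29 and 0.47 for interferon and -0.14 and -0.21 for alveolar markers (-0.12 without it). Further lists called at the preset correlation were G1/S (median 0.15), oxidative phosphorylation (-0.09) and ribosomal proteins (-0.08), all lost with an estimated correlation (smallest adjusted p = 0.38). With the block at the preset correlation G1/S kept its call (adjusted p = 0.0061), and oxidative phosphorylation (0.75) and ribosomal proteins (0.47) did not. The interferon list had a median of 0.17 with no single gene called over all genes or over the list alone by limma (adjusted p = 0.00069, and adjusted p = 0.76 with an estimated correlation).

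The 10 largest increases were in Sult1c1 (2.02), Sftpc (1.80; a dimmer probe set gave -0.18), Tnc (1.78), Ddah1 (1.74), the intermediate filament gene Vim (1.71), Myl4 (1.65), Fam81a (1.60), Ankrd66 (1.54), the dynein heavy chain gene Dnah1 (1.51) and Sult1c2 (1.49). The 10 largest decreases were in Cxcl1, Ager, Ndnf (-2.25), Cldn18 (-2.05), Gpm6a (-2.01), Kcne2 (-1.99), Spock2 (-1.93), Igfbp2 (-1.85), Acaa1b (-1.76) and Aass (-1.68); for Cldn18 and Gpm6a the Mmp7-null level lay at background, and other probe sets gave less for Gpm6a (-0.86) and Clca3a2 (0.23). Alveolar markers were lower in 5 of 15 cases and higher in 1 (5 and 2 adjusted over the list alone; adjusted p = 0.2), with Hopx at -0.66 and Cav1 at -0.63. Of 22 mucus genes 3 were higher, 4 lower and 15 did not pass, and the list was not called (adjusted p = 0.68), with Clca3a2 at 1.41 and Agr2 at -0.74. The macrophage marker Cd68 was at -0.92. Of the metalloproteinase list Timp1 (1.32) and Adam8 (0.29) were higher, and Mmp23 (-0.66), Adam9 (-0.27) and Adam17 (-0.19; other probe sets gave 0.08 and -0.18) were lower. On chromosome 9 Casp4 was at -1.41 (SE 0.11, adjusted p = 1.5e-05), Sesn3 at -0.41 and Casp1 at -0.39. Elmod1 (0.65) and Cep57 (0.35, with another probe set at 0.18) were higher. Elmod1 is in the fixed list but does not lie within 40 measured genes of Mmp7. Pdgfd was at -1.06 and did not pass (adjusted p = 0.058).

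In all, 1130 genes passed, 599 higher and 531 lower; with each array centred on its median the split was 600 higher and 316 lower. The 8 scratched arrays alone gave 527. With the spike-in set as a block 252 passed (153 higher, 99 lower), within the Phe arrays (2 against 1) 223 passed, and Lys against Trpn arrays gave 432. Of 43 called genes named here 22 passed with the block: Myb, Deup1, Lrrc23, Rsph1, Cxcl1, Ager, Cldn18, Casp4, Cav1, Hopx, Igfbp2, Spock2, Aass, Acaa1b, Clca3a2, Ect2, Fam81a, Myl4, Sftpc, Timp1, Tnc and Vim. The others lost their call. The median ratio of the 43 differences was 0.97, and the Phe arrays gave the same sign for 378 of the 432 genes (87.5%). Over all genes the differences of these separate sets of arrays correlated with r = 0.56. Uninjured and scratched genotype differences correlated across genes with r = 0.60 and a slope of 0.67. Both called 423 genes, 264 higher and 151 lower in both, against 13.8 and 13.3 expected if calls were independent over all genes. Calls are not independent, since both comparisons share each gene's estimated spread and the spike-in sets, and dim genes are seldom called. The overlap is therefore not independent evidence of a genotype difference.

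**Figure D1:**
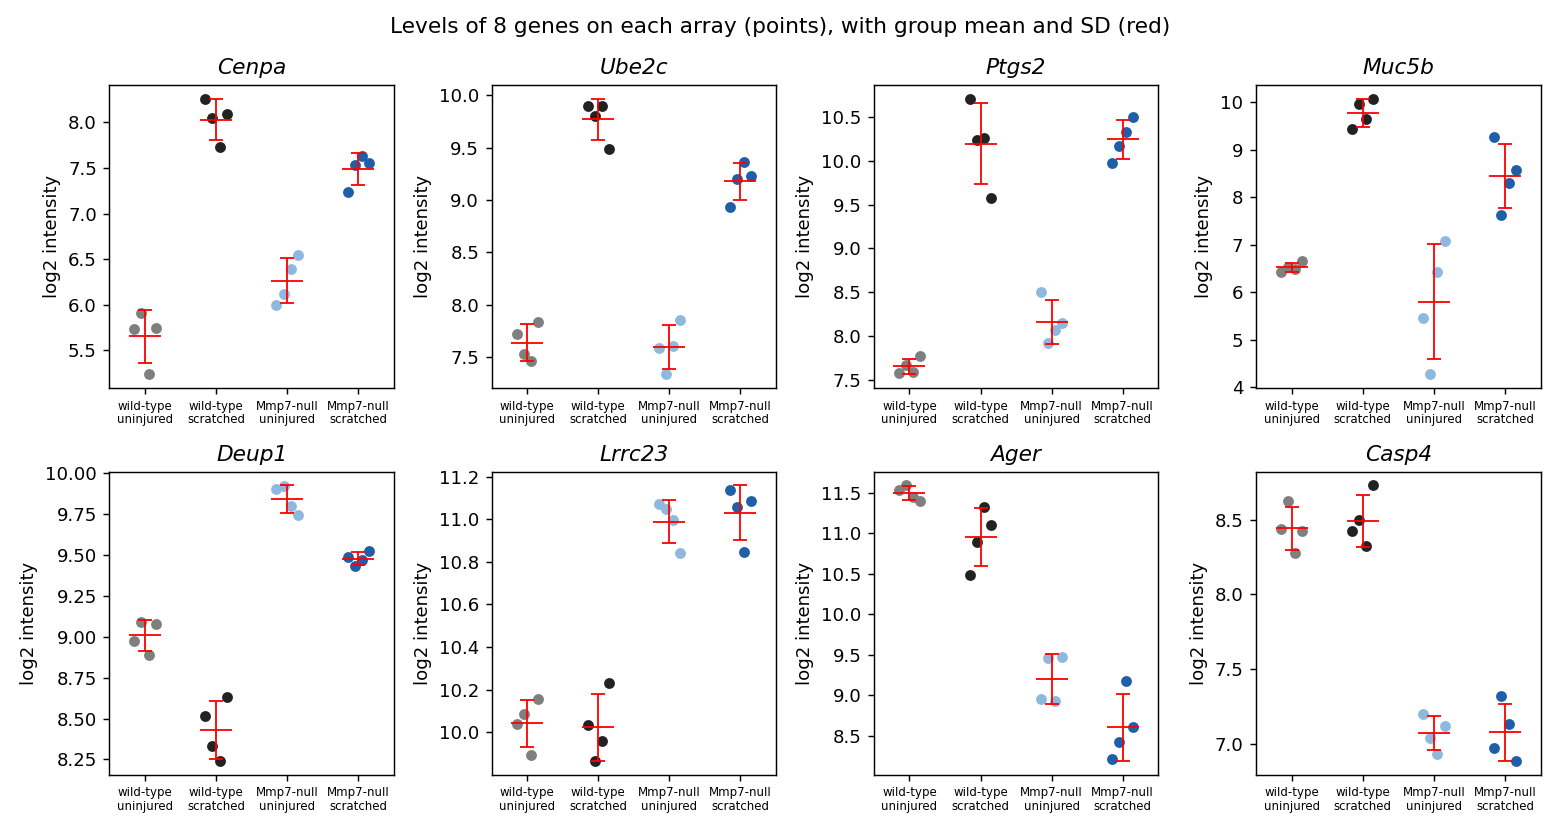
Log2 intensity (vertical axes) of 8 genes on each of the 16 arrays, by group (horizontal axes); points are arrays, red marks are group means with SD. Cenpa went from a mean of 5.66 to 8.03 on scratching in wild-type cultures and from 6.26 to 7.49 in Mmp7-null ones, while Casp4 lay near 8.44 in uninjured wild-type and 7.07 in uninjured Mmp7-null cultures.

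The last comparison asks which scratch responses differ between the genotypes. Of 47 mitotic genes 2 passed: the difference of responses was -1.05 for the kinesin Kif2c (SE 0.18, adjusted p = 0.043; a dimmer probe set gave -0.43 and did not pass even unadjusted) and -0.51 for Cks2 (SE 0.07, adjusted p = 0.019). Agr2 differed by -1.1 (SE 0.19, adjusted p = 0.043), and Slpi, an antiprotease of airway secretions, by -0.94 (SE 0.11, adjusted p = 0.0061): Slpi had means of 10.13 and 10.45 in uninjured and scratched wild-type cultures and 10.17 and 9.56 in Mmp7-null ones. Srebf2 differed by 0.67 (SE 0.11, adjusted p = 0.037; its other probe set gave 0.12).

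When adjusted over the list alone 28 of the 47 mitotic genes had a lower response; the median difference was -0.53 (adjusted p = 2.1e-27, and adjusted p = 0.065 with an estimated correlation). Within the Phe arrays, which hold 1 wild-type array per state, it was -0.62. The mean level of these genes was 6.43 ± 0.08 in uninjured and 7.52 ± 0.13 in scratched wild-type cultures, and 6.71 ± 0.08 and 7.25 ± 0.13 in Mmp7-null ones. By exact permutation tests the genotypes differed in uninjured cultures (p = 0.0286, the smallest possible), and the difference in scratched ones did not pass (p = 0.0571). The interferon list had a median difference of 0.42 with no gene called by limma over all genes or over the list alone (adjusted p = 3e-12, and adjusted p = 0.39 with an estimated correlation). Multiciliated genes had a median of 0.18 (1 adjusted over the list alone; adjusted p = 1.1e-09, and adjusted p = 0.4 with an estimated correlation) and oxidative phosphorylation genes of -0.14 (adjusted p = 1.7e-08, and adjusted p = 0.4 with an estimated correlation).

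Further genes with a lower response in Mmp7-null cultures included Cd68 (-1.12), the potassium channel Kcnj15 (-1.04), the clock-controlled transcription factor Dbp (-0.95), Cdca3 (-0.89), the cytokinesis gene Cep55 (-0.83; a dimmer probe set gave -0.46), Arrdc3 (-0.78) and the fatty acid binding protein Fabp5 (-0.78). Rasl11a (1.18), Med24 (1.04), Mex3b (0.91) and Samd4 (0.88; other probe sets gave 0.53 and 0.39) had a higher one. Rasl11a went from 4.60 to 3.25 in wild-type cultures but lay at 3.30 and 3.12 in Mmp7-null ones, close to background, where little fall can be measured. In all, 24 genes passed, 5 higher and 19 lower, and 1417 had an unadjusted p under 0.05. Median centring gave 5 genes (2 higher, 3 lower). Leaving out single arrays gave 12 without Mmp7-null uninjured replicate 3, 8 without Mmp7-null scratched replicate 3, 15 without Mmp7-null scratched replicate 4, 12 without wild-type uninjured replicate 1, 14 without wild-type scratched replicate 1 and 12 without wild-type scratched replicate 2. With the spike-in set as a block, which leaves these differences unchanged, 18 genes passed. Of the 16 named here 10 kept their call, and Agr2 (adjusted p = 0.089), Kif2c (0.086), Cd68 (0.069), Cdca3 (0.069), Srebf2 (0.059) and Cep55 (0.055) did not.

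**Figure D2:**
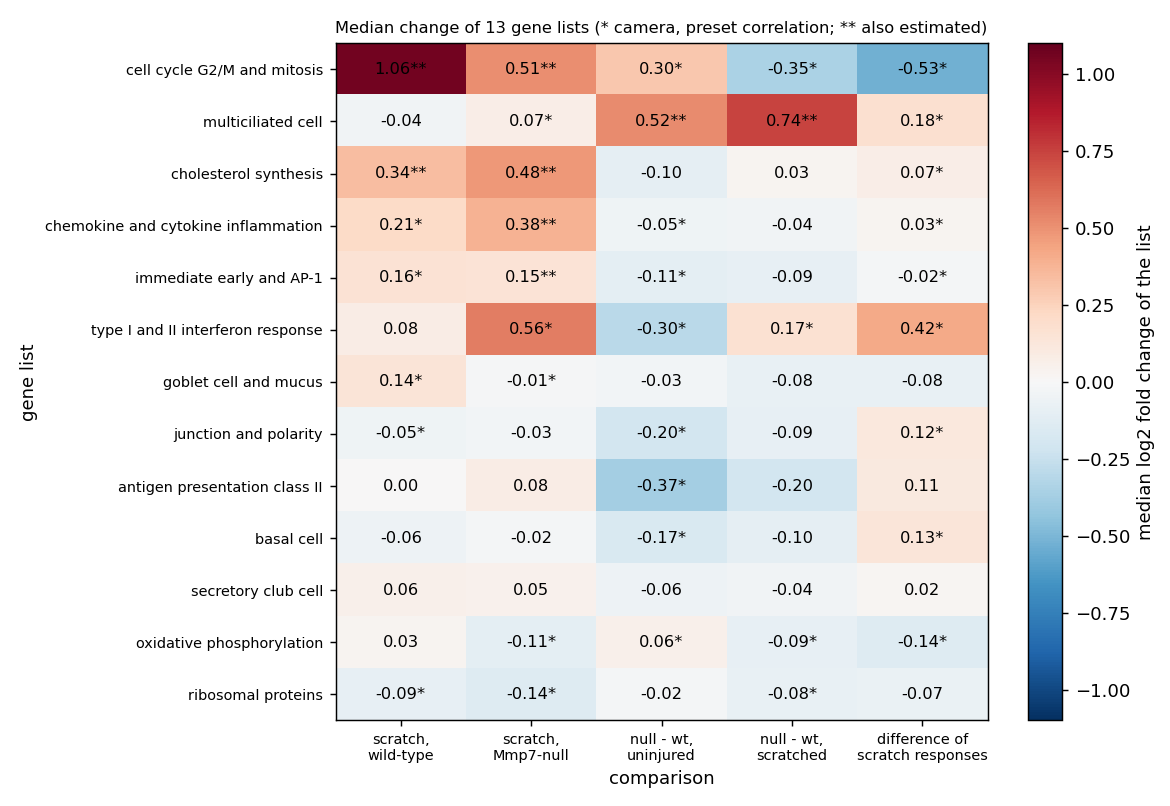
Median log2 fold change of 13 gene lists (vertical axis) in the 5 comparisons (horizontal axis); colour and number give the median, 1 star marks a call at the preset correlation and a double star a call that also holds with an estimated correlation. Mitotic genes had medians of 1.06 and 0.51 for scratch, and multiciliated genes of 0.52 and 0.74 for genotype.

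**Figure D3:**
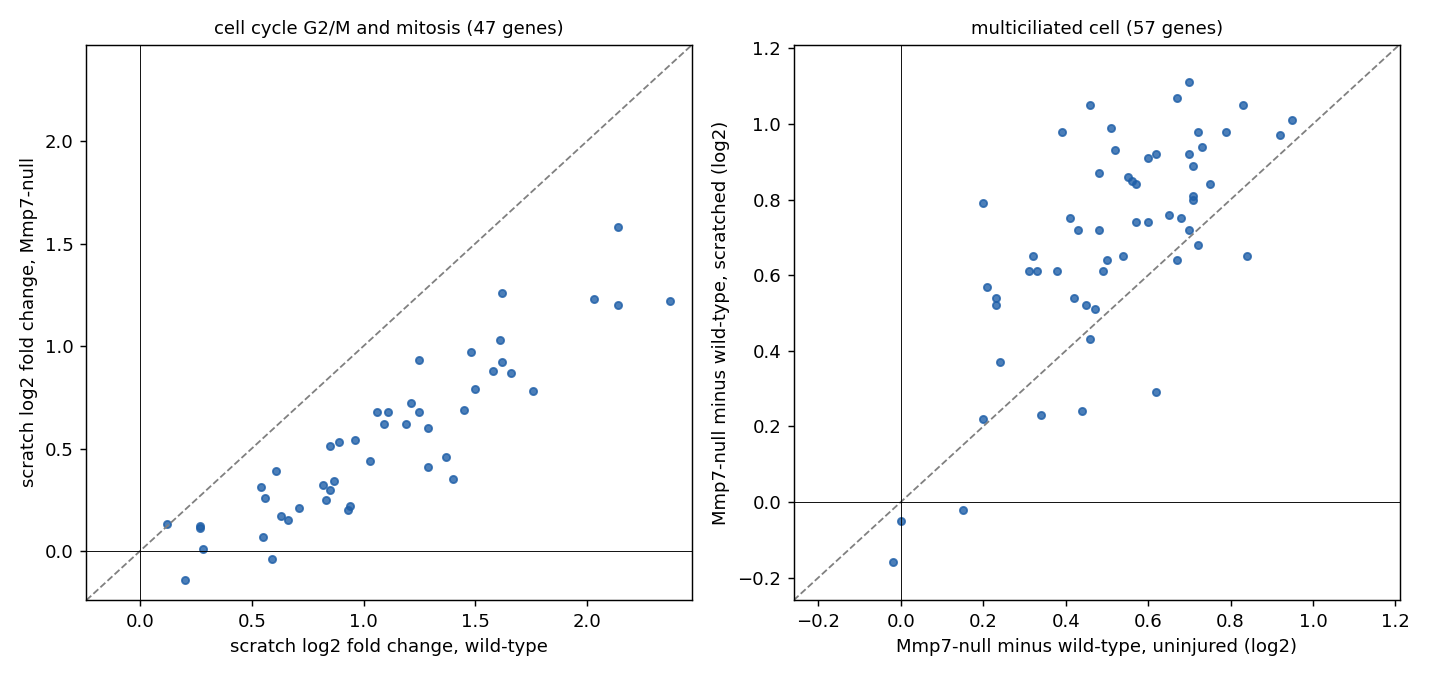
Each point is a gene. Left: scratch log2 fold change of 47 mitotic genes in wild-type (horizontal) and Mmp7-null cultures (vertical); 46 lie below the dashed line of equality. Right: Mmp7-null minus wild-type log2 difference of 57 multiciliated genes in uninjured (horizontal) and scratched cultures (vertical); 54 lie above 0 in both.

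The Mmp7 transcript could not be used to check the genotypes. Its 1 probe set lay between 2.13 and 2.59 on all 16 arrays, below the background limit of 2.97. Wild-type cultures, scratched ones included, thus gave no Mmp7 signal above background (means of 2.16 uninjured and 2.17 scratched). The genotype comparisons therefore rest on the labels, and the arrays do not show that the cultures compared differed in Mmp7 RNA. Mmp7-null minus wild-type was -0.01 in uninjured cultures (exact permutation p = 0.543, adjusted p = 0.99) and 0.14 in scratched ones (exact permutation p = 0.143, adjusted p = 0.22); scratching changed it by 0.01 in wild-type and 0.16 in Mmp7-null cultures, and the difference of these was 0.15 (adjusted p = 0.73). Whether the probes lie in the deleted part of the gene is not stated.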

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

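The comparison of multiciliated with other cell types, the level test of mitotic genes in scratched cultures, the present form of their spike-in test, all tests of Casp4, Pdgfd and the region around Mmp7, the use of the spike-in set as a block and the mean differences of lists with their errors were chosen after the results had been seen. Some of these replaced a first form once its value was known. The comparison of cell types first rested on the basal cell list alone, and the spike-in test of mitotic genes also on the block, which could not move their difference. The spike-in test of chromosome 9 first took Casp4 and Pdgfd together and was to count for the spike-in set if either kept under 0.5 of its size; Pdgfd, at 0.48, met that, and the genes were then tested apart. The test of the region first included both genes, and in that form it passed in both states. The multiciliated median without chromosome 9 members was set beforehand and first read as excluding a strain-derived segment; that reading was dropped afterwards, since few members lie there.

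Of 57 multiciliated genes 34 were higher in uninjured and 47 in scratched Mmp7-null cultures, with list medians of 0.52 and 0.74. The tables argue against the spike-in set as the whole cause, since with it as a block the mean difference was 0.54 (SE 0.11) in uninjured and 0.71 (SE 0.11) in scratched cultures, and within the Phe arrays (1 wild-type array per state) the smaller of the states' medians kept 0.87 of its size. The loss of 1 other cell type would raise all remaining types alike, but the club cell list had a median of -0.06 (mean difference -0.11, SE 0.07), the goblet list of -0.03 and the basal list of -0.17 (mean difference -0.21, SE 0.04), against a mean of 0.52 (SE 0.07) for the multiciliated list. A larger share of multiciliated cells, more transcript per cell, and differences between the donor animals or culture batches of the genotypes were not tested and stay open. A strain-derived segment around Mmp7 cannot be told apart from the deletion either: 3 of the 57 members lie on chromosome 9, too few for the median without them (0.52) to decide although it met the bound set beforehand, and a flanking gene acting on cilium genes elsewhere was not tested.

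As a list, mitotic genes had a smaller scratch response in Mmp7-null cultures, with a median difference of -0.53, but 2 of 47 genes passed and the call is lost with an estimated correlation (adjusted p = 0.065). The tables argue against 1 outlying array, since the median nearest to 0 on leaving out an array was -0.47. They argue against the spike-in set, which is spread alike over both states of a genotype: the median was -0.62 within the Phe arrays, and the mean difference was -0.64 (SE 0.20) there and -0.54 (SE 0.15) between Lys arrays of Mmp7-null and Trpn arrays of wild-type cultures. Whether a higher start alone accounts for the smaller rise cannot be told apart from a lower mitotic level after injury: the mean difference was 0.28 (SE 0.08) in uninjured cultures and -0.27 (SE 0.08) in scratched ones, or 0.20 (SE 0.11) and -0.35 (SE 0.11) with the set as a block, so the scratched values speak for a lower level, but the exact permutation p of 0.0571 with 4 against 4 missed its bound and the scratched list call is lost with an estimated correlation (adjusted p = 0.62). The timing of RNA isolation after the scratch and the share of cycling cells were not tested.

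Casp4, near Mmp7 on chromosome 9, was lower in Mmp7-null cultures in both states (-1.37 and -1.41), and Pdgfd passed in uninjured cultures (-1.20, SE 0.31) but not in scratched ones (-1.06, adjusted p = 0.058). For Casp4 the tables argue against the spike-in set, with at least 0.84 of its size kept within the Phe arrays; for Pdgfd the set cannot be told apart from genotype, since 0.48 was kept in uninjured cultures (-0.58, SE 0.54) but its difference was -1.51 in scratched ones, and with the set as a block the uninjured call ended through a larger standard error (-1.11, SE 0.46, adjusted p = 0.47). A flanking segment from another mouse strain is a candidate explanation: of 41 expressed genes within 40 measured genes of Mmp7 on either side (23 exist on one side), 8 passed in uninjured cultures (19.5%, against 7.40% elsewhere, Fisher's exact p = 0.0096) and 9 in scratched ones (22.0% against 9.47%, p = 0.013). Without Casp4 and Pdgfd, which drew attention to the region, 6 of 39 passed (Fisher's exact p = 0.066) and 8 of 39 (p = 0.028), and several of these are cilium genes (Deup1, Cfap300, Cep295), so the question stays open. The strain in which the deletion was made is not stated.

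Other splits of the arrays were counted for every comparison, with the real split included. For genes, 1 of the 35 splits (the real one) gave as many calls in each of the 4 simple comparisons: 883 in wild-type scratch with a highest other of 1, 859 in Mmp7-null scratch with 5, 872 for genotype in uninjured cultures with 1, and 1130 in scratched cultures with 25. For the difference of responses, 1 of 100 relabelings gave 24 genes or more, with a highest other of 8. No other split or drawn relabeling thus reached the gene counts, but chance is not excluded. For the simple comparisons 1 of 35 is the smallest share that the splits can give. The other splits also mix the groups compared, which adds any real difference to the spread and lowers their counts. Cultures that share an animal or a batch would not show in these counts. For lists at the preset correlation, 1 of 35 splits reached the 14 calls of wild-type scratch (highest other 12), but 3 of 35 reached the 17 of Mmp7-null scratch (highest other 19), 2 of 35 the 18 of genotype in uninjured cultures (highest other 18) and 27 of 35 the 5 of genotype in scratched cultures (highest other 16). Chance is not excluded for the last 3 of these numbers either. Splits that keep most arrays of a group together keep part of any real difference, so they cannot show that these calls are due to chance. Each number was adjusted within its comparison.

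The 24 genes whose scratch response differed between genotypes had log2 differences of -1.12 (Cd68), -1.1 (Agr2), -1.05 (Kif2c), -1.04 (Kcnj15), -0.95 (Dbp), -0.94 (Slpi), -0.89 (Cdca3), -0.83 (Cep55), -0.78 (Arrdc3 and Fabp5), -0.70 (Slc5a3), -0.68 (Avpi1), -0.67 (Prss8), -0.65 (Sgo2a), -0.57 (Sec23b), -0.51 (Cks2), -0.46 (Sdhaf4), -0.43 (Kcnk1), -0.30 (Hnrnpc), 0.67 (Srebf2), 0.88 (Samd4), 0.91 (Mex3b), 1.04 (Med24) and 1.18 (Rasl11a). The 12 lists whose response differed at the preset correlation had median differences of -0.53 (mitosis), -0.14 (oxidative phosphorylation), -0.02 (immediate early and AP-1, whose mean was 0.05), 0.03 (chemokines), 0.06 (Wnt and Notch), 0.07 (hypoxia), 0.07 (cholesterol), 0.10 (TGF-beta), 0.12 (junctions), 0.13 (basal cell), 0.18 (multiciliated) and 0.42 (interferon). With an estimated correlation none of the 12 passed; the smallest adjusted p was 0.065, for mitosis.

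Single arrays far from the other 3 of their group, by the gap to the nearest array as a share of the group's range, were seen for 22 of 396 combinations of gene and group and 11 of 136 of list and group; chance gives about 5%. On wild-type scratched replicate 3 the shares were 0.84 (Acta2), 0.86 (Ccnb2), 0.85 (Mmp7), 0.85 (Clca3a2), 0.87 (Acaa1b), 0.92 (fibroblast markers), 0.94 (smooth muscle and cartilage markers) and 0.88 (thyroid and oesophageal markers). On Mmp7-null scratched replicate 1 they were 0.85 (Ccnb2), 0.98 (Cav1), 0.83 (Serpinb2), 0.98 (Adam17) and 0.88 (cholesterol synthesis). On the other wild-type scratched arrays they were 0.84 (Kcne2, replicate 2), 0.85 (Myb, replicate 1), 0.99 (unfolded protein list, replicate 1) and 0.85 (oxidative phosphorylation, replicate 4), and on the other Mmp7-null scratched arrays 0.91 (Rsph1, replicate 2) and 0.85 (Kcnj15, replicate 3). In uninjured wild-type cultures they were 0.84 (Dclk1), 0.83 (Nfkbiz), 0.93 (H2-Aa) and 0.86 (mitosis list) on replicate 3, 0.84 (Id3) and 0.84 (junction list) on replicate 4, and 0.85 (Ppp2r2b), 0.83 (H2-Ab1) and 0.85 (thyroid and oesophageal markers) on replicate 1. In uninjured Mmp7-null cultures they were 0.90 (Timp1, replicate 4), 0.86 (Yap1, replicate 1), 0.86 (Cks2, replicate 2), 0.94 (wound edge list, replicate 3) and 0.92 (class II list, replicate 1).

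The spiked-in control transcripts, outside the measured genes, were present on some arrays and absent on others. Where present, their mean log2 level was 15.07 for Lys (4 arrays), 15.42 for Phe (6 arrays) and 14.80 for Trpn (6 arrays).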

How the results depend on the processing

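The spike-in set block, the repeat without the 3 doubtful arrays and the criterion for these arrays were chosen after the data had been seen. The cause of each change below was not tested, except where fewer arrays or a stricter threshold make it plain.

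Genes changed by scratch in wild-type cultures numbered 883, and 591 to 1125 leaving out each array; array weights gave 1405 and a fold threshold of 1.5, which is stricter, gave 307. In Mmp7-null cultures 859 changed, and 516 to 943 leaving out each array; the 8 arrays compared gave 402 and the fold threshold 234. The genotype difference in uninjured cultures held 872 genes and 480 to 1049 leaving out each array, with 57 under the spike-in set block, where the standard error grows 1.47 times, 1310 without the 3 doubtful arrays and 296 with the fold threshold. In scratched cultures it held 1130 genes and 809 to 1135 leaving out each array, with 252 under the spike-in set block, 527 from the 8 arrays compared, 1745 with array weights and 440 with the fold threshold. Genes whose response differed numbered 24, and 8 to 28 leaving out each array; the replicate number as a block gave 14, dim genes left out 37, all probe sets singly 39, array weights 100, repeated quantile normalization 49, median centring 5 and the 3 doubtful arrays left out 50. The total counts under the other alternatives stayed within 1.5 times, a bound that was not applied to each direction. Without the 3 doubtful arrays 787 genes passed for genotype in scratched cultures. Of these 504 were higher and 283 lower, against 599 and 531 with all arrays, so the lower genes lost more calls. Median centring moved the median of all genes by less than 0.05 on the log2 scale in each comparison.

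List calls numbered 64 and 58 to 69 leaving out each array, but 8 with an estimated correlation; the other alternatives gave between 46 (fry) and 67. The multiciliated lists of both genotype comparisons and the mitotic lists of both scratch comparisons passed under every alternative run, with the largest adjusted p being that with an estimated correlation (0.042, 0.028, 0.0081 and 0.029). The list for G1/S in wild-type scratch turned direction without the 3 doubtful arrays (adjusted p = 0.75). The correlation of the scratch responses was 0.60, and 0.56 to 0.60 leaving out each array; it was 0.62 without dim genes, 0.61 with the mean of probe sets, 0.51 over all probe sets, 0.56 with array weights and 0.54 without the 3 doubtful arrays.

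Changes of sign were counted only for pairs of gene and comparison called in the main setting or in the alternative. Of the 606 named pairs, 5 changed sign in this way, all through another choice of probe sets. With the mean of probe sets it was Tubb4b in Mmp7-null scratch (-0.03). Without probe sets marked as less specific it was Rps24 in Mmp7-null scratch (0.38, adjusted p = 0.0089) and in the scratched genotype comparison (0.59, adjusted p = 0.00034). In that setting Uqcrq in the uninjured genotype comparison (-0.04) and Acta2 in the scratched one (-0.07) changed too. The spike-in set block took 182 of the 606 pairs below the threshold, the fold threshold 180 and the 8 arrays compared 117. The difference of responses needs all 16 arrays and has no value from 8. Levels near the background of 2.97 limit what can be said of Mmp7, Cldn18 and Gpm6a.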

Other observations

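The gene sets for alveolar type 1 cells and the circadian clock in this part, and the tests around Mmp7 by windows along the genome, were chosen after the results had been seen.

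Besides the markers named among the largest changes, some further genes of the alveolar type 1 cell, the flat gas-exchange cell, were lower in Mmp7-null cultures. The fixed list of alveolar markers was not called (adjusted p = 0.057 uninjured and 0.2 scratched), and no test was made of the set used here. Of its 20 genes, 11 were lower in uninjured and 15 in scratched Mmp7-null cultures. For 9 of the 20 the difference had been seen when the set was put together, so these counts are not independent evidence; of the 11 others, 4 were lower in uninjured and 6 in scratched cultures. The lower genes of the whole set included, next to Ager and Gpm6a, Clic5 (-1.21, SE 0.15, adjusted p = 0.00075, uninjured), Akap5 (-1.01, SE 0.14), Col4a3, a basement membrane collagen (-0.98, SE 0.13), Cyp2b10 (-0.57, SE 0.09) and Emp2 (-0.50, SE 0.08). Under the spike-in set block Col4a3 kept its uninjured call (-1.12, adjusted p = 0.045), and Clic5 (-1.16, adjusted p = 0.055), Akap5 (-1.01, 0.068), Cyp2b10 (-0.40, 0.13), Emp2 (-0.41, 0.14), Spock2 (-1.87, 0.06) and Hopx (-0.27, 0.48) did not. In scratched cultures Col4a3 (adjusted p = 0.042), Clic5 (0.044), Akap5 (0.019), Cyp2b10 (0.023), Spock2 (0.039) and Hopx (0.036) kept their calls under it, and Emp2 (0.051) and Gpm6a (0.065) did not. The water channel Aqp5 was at -0.15 in uninjured (adjusted p = 0.35) and -0.41 in scratched cultures (adjusted p = 0.0032). Its scratched call ended under the block (-0.26, adjusted p = 0.17). So did the scratched call of Sema3e, at -0.45 without the block (adjusted p = 0.034) and -0.55 with it (adjusted p = 0.16). Krt7 (-0.07 in both) and Pdpn (-0.05 and -0.12) did not pass. The alveolar type 2 gene Sftpc was higher by its brightest probe set, while a dimmer one gave -0.08 and -0.18.

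Of 15 measured clock genes 3 were higher and 1 was lower in uninjured Mmp7-null cultures, and 1 was higher and 2 were lower in scratched ones; the others did not pass, and no test of the set was made. In uninjured Mmp7-null cultures Dbp (0.64, SE 0.10, adjusted p = 0.0023), Per3 (0.59, SE 0.14, adjusted p = 0.026) and Nr1d2 (0.38, SE 0.07, adjusted p = 0.0095) were higher and Arntl, the gene of the activator BMAL1, was lower (-0.92, SE 0.14, adjusted p = 0.0017). In scratched cultures Cry1 was higher (0.45, SE 0.09, adjusted p = 0.0092), and Nr1d1 (-0.68, SE 0.11, adjusted p = 0.0028) and Arntl (-0.57, SE 0.14, adjusted p = 0.022) were lower. Under the same block Dbp kept its call (0.77, adjusted p = 0.044). The calls of Per3 (0.65, adjusted p = 0.21), Nr1d2 (0.33, 0.3), Arntl (-0.81, 0.13 uninjured and -0.46, 0.38 scratched), Cry1 (0.34, 0.29) and Nr1d1 (-0.64, 0.1) ended, most with differences of similar size. The clock time of RNA isolation is not stated.

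Along the genome, 0.877% of 10838 windows of 41 consecutive expressed genes held as many called genes as the region around Mmp7 in uninjured cultures, and 1.27% in scratched ones. Without Casp4 and Pdgfd the shares were 6.73% and 2.56% of 10878 windows of 39 genes. Windows overlap and are not independent.

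Transcripts that report sex and strain did not separate the genotypes by the threshold. None of the strain reporters is among the measured genes around Mmp7, so they cannot test a flanking segment from another strain. The strain reporter Nlrp12 lay between 2.49 and 2.68, at background. Xist lay between 11.89 and 12.57 on all arrays and the Y-linked gene Eif2s3y between 2.77 and 2.97. Nnt lay between 8.20 and 8.66, with genotype differences of -0.07 in uninjured cultures (adjusted p = 0.94) and -0.07 in scratched ones (adjusted p = 0.58).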
